A study of Sus scrofa with 6 samples.

How the data were processed

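RNA was taken from the prefrontal cortex of 3 VPA-exposed and 3 control pigs aged 3 months. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. How RNA species were selected, strandedness, read length, aligner, counting tool, genome build and annotation are not given in the sources used here. Groups came from the labels' treatment entries, and libraries are named by animal number. The numbers are not shared between groups, so no pairing was possible. Litter, sex and sequencing batch are not given in the sources used here. The labels name separate animals, but not whether they came from separate litters.

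The authors deposited raw counts per gene and FPKM per gene for each library, per the file headers and names. Every one of 97071 nonzero deposited FPKM values equalled the count divided by the file's total and by a whole-number gene length, on the usual FPKM scale. Each gene's length was the same in all libraries (relative tolerance 0.001), so both units hold the same measurement. Both list 17201 genes. Of these names, 17177 matched symbols of the RefSeq gene table of the Sscrofa11.1 assembly, and 24 had been turned into dates, as spreadsheet programs do; these were kept in library sizes and not named. As the build behind the counts is not given in the sources used here, no coordinates are printed and the table served only for names; 5 list members were matched through its synonyms. Mitochondrially encoded genes are not analysed here. No pair of libraries agreed within sampling noise: the chi-square of counts per degree of freedom was 5.91 to 13.2 over the 15 pairs.

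Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with its defaults (14373 genes kept, 2828 not tested), TMM factors (0.993 to 1.01), glmQLFit and glmQLFTest with no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. Genes past it are termed called. Standard errors of log2 fold changes were derived from the F statistic. Values are CPM as mean ± SD. The common biological coefficient of variation was 9.01%. With 3 against 3 libraries the fit has 4 residual degrees of freedom. The test sets each difference against the spread between these animals, with dispersion information shared across genes. Reads shared by near-identical genes or by overlapping genes cannot be separated here, as the counting is not given.

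Of 46 gene lists fixed before the data were examined, 44 had at least 5 measured members and were tested with camera on the edgeR fit (preset correlation 0.01, Benjamini-Hochberg over the 44); camera with an estimated correlation and fry stood beside it. Mitochondrially encoded genes had too few measured members, and the list of X-inactivation and Y-linked genes was used only to describe the animals. The named genes follow a rule fixed before the data were examined: the 10 largest called rises and falls with a symbol, a mean of at least 1 CPM and groups that do not overlap; from each list that is called or has a called member, up to 3 called members, or otherwise the 2 with the lowest p in its direction, as values only. To these come 12 fixed genes. Genes outside it are named where they describe a library. Some genes that the rule selects are not reported here. Principal components and correlations used log2 CPM with a prior count of 2.

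Simulated counts for the VPA against control comparison, drawn from the real means, dispersions and library sizes, were run through the same functions. In them 200 genes were changed, and a further list of genes, left out of the recovered shares below, was raised 1.25-fold. Over 14273 genes edgeR recovered 22.7% of 1.25-fold, 67.2% of 1.5-fold and 81.8% of 2-fold changes, and 6.11% of its calls were false. In a separate run over 14272 genes with no gene changed it made 0 calls. The simulated genes vary independently, so the simulation tests neither camera's preset correlation nor calls where genes vary together across animals. Of the other tools described below, DESeq2 made 141 simulated calls and limma on FPKM 105, where edgeR made 131. In the real libraries they made 444, 2 and 52, so the simulated shares need not hold for the real calls.

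Alternatives were other scaling (RLE, upper quartile, library size only), other filters (none, mean of at least 1 CPM), and DESeq2 1.42.0 with defaults. Others were limma 3.58.1 (voom, and trend on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, also with a pseudocount of 0.1 and without the filter), robust dispersion, other thresholds, EIF1AY as a covariate (the only measured Y-linked gene of the fixed list), and each library left out. Added after seeing the data were the 4 libraries with EIF1AY counts only, an oligodendrocyte score (the mean log2 CPM of that list) as a covariate, and DESeq2 without VPA 393 and on those 4 libraries.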

Results

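Prefrontal cortex RNA was sequenced from 6 pigs (Sus scrofa) aged 3 months. Per the labels, 3 animals (391, 392 and 393) had been exposed in early gestation to valproic acid (VPA) at 75 mg/kg. The other 3 (401, 402 and 408) were controls, labelled as given no treatment. VPA is an anticonvulsant that inhibits histone deacetylases. The series presents the exposure as a pig model of autism, and its design implies 1 comparison, of gene expression in cortex between VPA and control animals. Total counts per library ran from 16285517 to 17989032 over 17201 listed genes, with 16127 to 16236 genes detected. Normalised counts are given as CPM, and 1 CPM stood for 16 to 18 reads. Pearson correlations of log2 CPM between libraries lay between 0.983 and 0.989, with a median of 0.987 within groups and 0.986 between groups.

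Few genes were called between VPA and control cortex in the main test, most of them with a change of less than 2-fold. Of 14373 genes tested, 52 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test (Benjamini-Hochberg), 40 higher and 12 lower in VPA, with a median size of 0.42 on the log2 scale. In the same test 2322 genes had an unadjusted p under 0.05, and DESeq2 called 444. The 52 therefore do not bound the number of genes that differ. TTR, which encodes the thyroid hormone carrier transthyretin, rose 5.87-fold, from 1.08 ± 0.424 CPM in controls to 6.33 ± 2.94 CPM in VPA (SD, n = 3 each, adjusted p = 0.041). It had 9.72 CPM in VPA 393, 4.44 in VPA 391, 4.83 in VPA 392 and 0.611 to 1.43 in controls. TTR is also in the fixed list of choroid plexus and ependymal markers. UBAP1L rose from 1.49 ± 1.06 to 7.46 ± 0.386 CPM (log2 fold change 2.33 ± 0.38 SE, adjusted p = 0.048; 2.95 without control 402). Over its 17 alternatives the log2 fold change of UBAP1L ran from 1.24 to 3.14, and it passed the threshold in 9. PHKG1, a catalytic subunit of phosphorylase kinase, rose from 3.64 ± 0.513 to 8.27 ± 1.19 CPM (log2 fold change 1.18 ± 0.18, adjusted p = 0.041). These were the only 3 called genes with a change of at least 2-fold.

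The other large rises were in better expressed genes. APLN, which encodes the peptide apelin, rose from 17.3 ± 3.24 to 32.9 ± 1.41 CPM (adjusted p = 0.040). NWD1 rose from 7.15 ± 1.36 to 13.8 ± 0.0519 CPM (adjusted p = 0.041). The log2 fold change was 0.93 ± 0.16 for TMEM26 and 0.82 ± 0.13 for CCDC88C, which encodes a Dishevelled-binding protein. It was 0.75 ± 0.12 for SCML1 and 0.66 ± 0.087 for ATP10B, a phospholipid flippase. PAMR1 had the lowest adjusted p of all genes (0.0037) and rose from 90.2 ± 3.28 to 135.0 ± 2.91 CPM (log2 fold change 0.58 ± 0.050).

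The 12 genes that fell included LDHA, GFPT2, SV2B and SH3GL2. LDHA, a lactate dehydrogenase subunit, went from 247 ± 9.05 CPM in controls to 189 ± 10.2 CPM in VPA (log2 fold change -0.39 ± 0.053, adjusted p = 0.040). GFPT2, an enzyme that feeds glucose into the hexosamine pathway, went from 44.2 ± 1.46 to 27.6 ± 0.800 CPM (-0.68 ± 0.071, adjusted p = 0.012). SV2B, a synaptic vesicle glycoprotein, went from 866 ± 43.2 to 680 ± 43.9 CPM (-0.35 ± 0.060, adjusted p = 0.048). SH3GL2, which encodes endophilin A1 of synaptic vesicle endocytosis, went from 426 ± 12.7 to 336 ± 15.7 CPM (-0.34 ± 0.051, adjusted p = 0.041). The muscarinic acetylcholine receptor gene CHRM3 had a log2 fold change of -0.36 ± 0.062 and the neuronal surface glycoprotein gene THY1 one of -0.31 ± 0.053. OSMR, the oncostatin M receptor gene, had one of -0.69 ± 0.12 and RPS6KC1 one of -0.41 ± 0.062. It was -0.38 ± 0.066 for PIP4K2C, a phosphoinositide kinase gene, and -0.35 ± 0.060 for OLFM3.

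**Figure D1:**
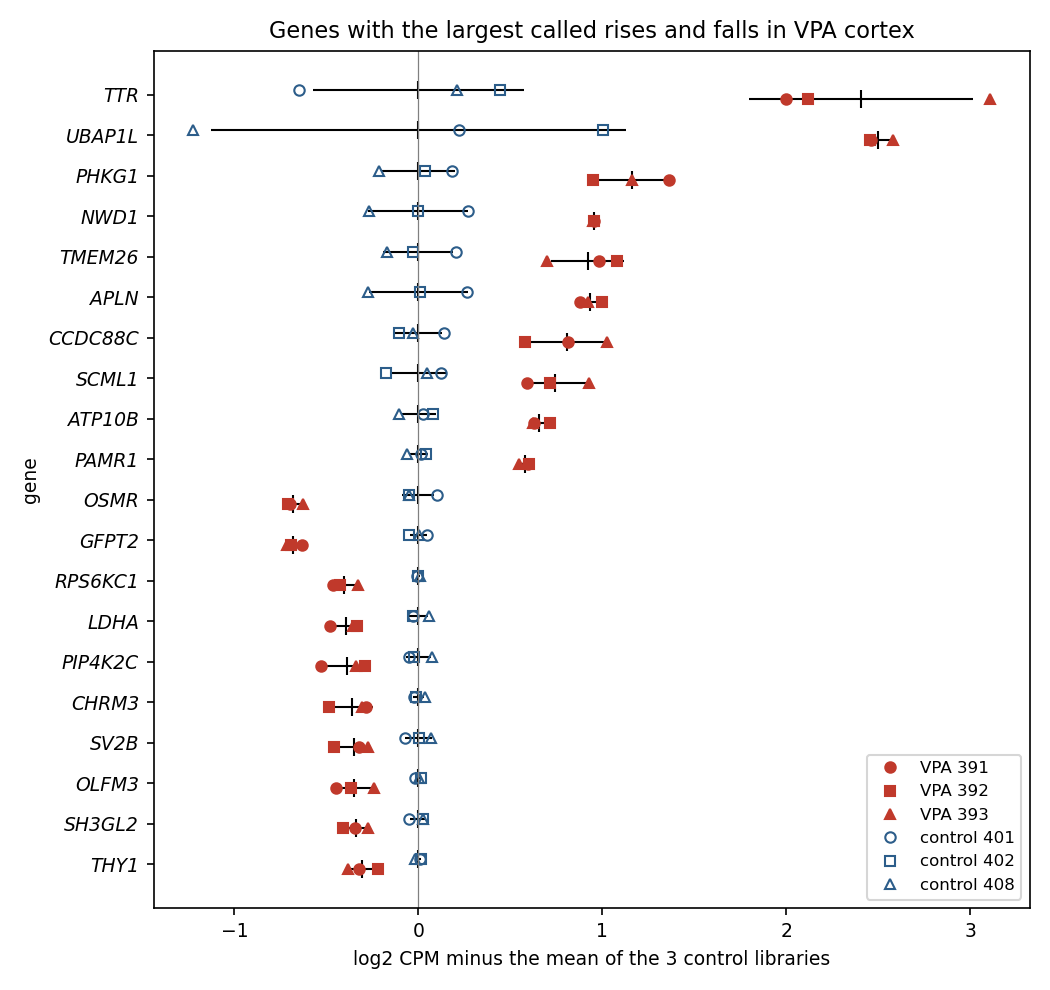
Each row is a gene and each point a library, at its log2 CPM minus the mean log2 CPM of the 3 control libraries; filled red points are VPA, open blue points control, and black bars show the group mean and SD (n = 3). The groups do not overlap in any of these 20 genes, which the naming rule required.

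All 52 called genes had groups that did not overlap, as did 3075 of the 14373 tested genes (21.4%, where chance gives 10%). The adjusted p of 44 of the 52 lay above 0.04, close to the threshold. The count fell to 0 without VPA 391 and without VPA 392, to 1 without VPA 393, to 5 without control 402 and to 2 without control 408. It was 66 without control 401, of which 27 were among the 52. In edgeR 1897 and 1723 genes had an unadjusted p under 0.05 without VPA 391 and VPA 392, and 2322 with all libraries. PAMR1 passed without VPA 393 and without each control in turn. DESeq2 called 444 genes, among them all 52.

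Markers of oligodendrocytes, the myelin-forming cells, stood higher in VPA cortex as a group. Of 25 measured, 23 had positive fold changes, with a median log2 fold change of 0.35 (camera, adjusted p = 1.27e-14 with a preset correlation; adjusted p = 0.44 with an estimated correlation). None passed over all genes tested, and 17 were higher when adjusted over the list alone. CLDN11, a tight junction gene of myelin, had 308 ± 26.5 CPM in VPA and 217 ± 32.8 in controls (adjusted p = 0.062). MAG, the myelin-associated glycoprotein gene, had 343 ± 18.8 and 258 ± 32.7 (adjusted p = 0.062). MBP, the myelin basic protein gene, had 8487 ± 842 and 7232 ± 1127 CPM, with overlapping groups (log2 fold change 0.23 ± 0.11, adjusted p = 0.31).

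Oligodendrocyte precursor and astrocyte markers lay in the same direction. Of 16 precursor markers 13 had positive fold changes (median 0.19, camera adjusted p = 3.93e-05; adjusted p = 0.44 with an estimated correlation). Over all genes none passed, and 7 were higher adjusted over the list alone. PTPRZ1, a receptor phosphatase gene, had a log2 fold change of 0.27 ± 0.062 (adjusted p = 0.078) and COL9A1, a collagen gene, 1.20 ± 0.29 (adjusted p = 0.090). Of 19 astrocyte markers 15 had positive fold changes (median 0.19, camera adjusted p = 0.00025; adjusted p = 0.45 with an estimated correlation). None passed over all genes and 7 were higher adjusted over the list alone. The glutamate transporter genes SLC1A3 (0.39 ± 0.083, adjusted p = 0.067) and SLC1A2 (0.18 ± 0.048, adjusted p = 0.11) were among them. GFAP, the astrocyte filament gene, had 2483 ± 385 CPM in VPA and 2389 ± 166 in controls (adjusted p = 0.83). Its log2 fold change was 0.06 and turned to -0.07 without VPA 392.

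Presynaptic, glutamatergic and GABA receptor lists lay the other way, while 20 of 26 GABAergic interneuron markers had positive fold changes (median 0.15, camera adjusted p = 0.091). Of 30 presynaptic vesicle genes 26 had negative fold changes (median -0.12, camera adjusted p = 1.33e-07; adjusted p = 0.44 with an estimated correlation). SV2B passed over all genes, and 12 were lower adjusted over the list alone. Of 19 glutamatergic neuron markers 15 were negative (median -0.15, camera adjusted p = 7.42e-06; adjusted p = 0.28 with an estimated correlation). None passed over all genes and 6 were lower adjusted over the list alone. The transcription factor gene NEUROD6 (-0.34 ± 0.069, adjusted p = 0.065) and the potassium channel gene KCNV1 (-0.29 ± 0.065, adjusted p = 0.073) had the lowest p of the list. SLC17A7, the vesicular glutamate transporter gene, had 1054 ± 48.8 CPM in VPA and 1151 ± 18.8 in controls (adjusted p = 0.25). Of 16 GABA receptor genes 13 were negative (median -0.16, camera adjusted p = 7.42e-06; adjusted p = 0.44 with an estimated correlation). Over all genes none passed, and 8 were lower adjusted over the list alone. Among these, GABBR2 had a log2 fold change of -0.27 ± 0.054 (adjusted p = 0.063).

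Smaller shifts were measured in ion channel and postsynaptic genes. Voltage-gated ion channel genes had a median of -0.07 (34 of 41 negative, camera adjusted p = 0.0013; adjusted p = 0.44 with an estimated correlation). It was -0.11 without control 401 and -0.04 without control 408. CACNA2D1 stood at -0.15 ± 0.047 (adjusted p = 0.14). Of the 41 genes, 0 passed over all genes or adjusted over the list alone. Postsynaptic scaffold and adhesion genes had a median of -0.05 (22 of 32 negative, camera adjusted p = 0.022; adjusted p = 0.44 with an estimated correlation). DLGAP1 stood at -0.21 ± 0.049 (adjusted p = 0.083) and SLITRK1 at -0.21 ± 0.060 (adjusted p = 0.13). None of the 32 passed over all genes, and 5 were lower and 1 higher adjusted over the list alone. The median was -0.03 without VPA 392 (adjusted p = 0.11), -0.04 without control 408 (adjusted p = 0.052) and -0.08 without VPA 393 (adjusted p = 0.0082).

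**Figure D2:**
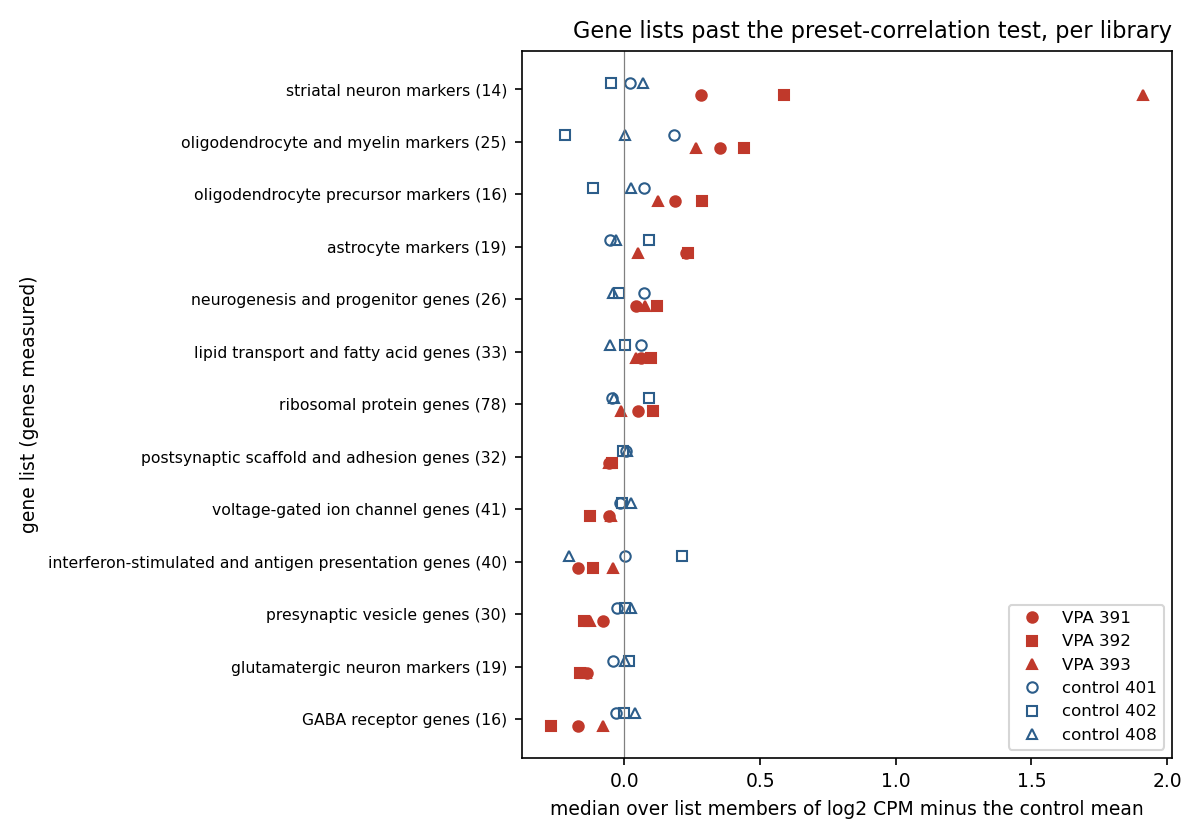
Each row is a gene list past the preset-correlation test, with its number of measured genes, and each point a library, at the median over the list's genes of log2 CPM minus the control mean; filled red points are VPA, open blue points control. VPA 393 lies at 1.91 for striatal neuron markers, against 0.28 in VPA 391 and 0.59 in VPA 392.

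Markers of striatal projection neurons, which belong to a region under the cortex, were high mainly in 1 VPA library. The list's median log2 fold change was 1.16, with 13 of 14 positive (camera adjusted p = 3.92e-07; adjusted p = 0.44 with an estimated correlation), and 0.47 without VPA 393 (camera adjusted p = 4.59e-05). None passed over all genes and 11 were higher adjusted over the list alone. The dopamine receptor gene DRD2 had 10.98 CPM in VPA 393, 1.86 in VPA 391, 1.65 in VPA 392 and 0.172 to 0.667 in controls (log2 fold change 3.65 ± 0.83, adjusted p = 0.077; 2.18 without VPA 393). RGS9, a regulator of G protein signalling, had 24.2 CPM in VPA 393, 11.16 and 11.02 in the other VPA libraries and 6.11 to 8.31 in controls (log2 fold change 1.12 ± 0.28, adjusted p = 0.10; 0.64 without VPA 393). In 12 of the 14 genes VPA 393 was the highest library.

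Interferon-stimulated and antigen presentation genes had a median of -0.08 (29 of 40 negative, camera adjusted p = 0.0091; adjusted p = 0.68 with an estimated correlation). Past the test over all genes were none, and 3 were lower adjusted over the list alone. IFI6 had 28.2 ± 5.35 CPM in VPA and 47.5 ± 9.32 in controls (adjusted p = 0.067). The antiviral GTPase gene MX1 had 140 ± 7.31 and 170 ± 12.7 (adjusted p = 0.077). The list's median varied within the controls, at 0.21 in control 402 and -0.20 in control 408 relative to their mean. Its fold change was -0.06 without VPA 391 (adjusted p = 0.13), -0.13 without VPA 393, -0.04 without control 402 (adjusted p = 0.53) and -0.18 without control 408. Neurogenesis and progenitor genes had a median of 0.08 (17 of 26 positive, camera adjusted p = 0.022; adjusted p = 0.44 with an estimated correlation). The intermediate filament gene VIM passed over all genes, from 343 ± 18.8 to 430 ± 8.05 CPM (log2 fold change 0.32 ± 0.052, adjusted p = 0.047), and 3 were higher adjusted over the list alone. That median was 0.04 without VPA 392 (adjusted p = 0.11), 0.07 without control 402 (adjusted p = 0.072), 0.05 without control 408 (adjusted p = 0.12) and 0.14 without control 401.

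Ribosomal protein genes had a median of 0.05 (63 of 78 positive, camera adjusted p = 0.022; adjusted p = 0.84 with an estimated correlation). RPL13 stood at 0.13 ± 0.053 (adjusted p = 0.26). Lipid transport and fatty acid genes had one of 0.07 (25 of 33 positive, camera adjusted p = 0.036; adjusted p = 0.44 with an estimated correlation). The apolipoprotein gene APOD stood at 0.31 ± 0.086 (adjusted p = 0.12) and the elongase gene ELOVL6 at 0.20 ± 0.072 (adjusted p = 0.20). In both lists 0 genes passed over all genes or adjusted over the list alone. The ribosomal median was 0.04 without VPA 391 (adjusted p = 0.058), 0.02 without VPA 392, control 401 or control 408 (adjusted p = 0.55, 0.48 and 0.38), 0.08 without VPA 393 and 0.09 without control 402. That of the lipid genes was 0.05 without VPA 392 (adjusted p = 0.13) and 0.06 without control 408 (adjusted p = 0.23).

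Histone deacetylase genes, whose products VPA inhibits, were compared one by one. HDAC1 rose from 14.0 ± 1.10 CPM in controls to 20.4 ± 0.142 CPM in VPA (log2 fold change 0.55 ± 0.095, adjusted p = 0.048), higher in 3 of 3 VPA animals than in any control. It passed in 6 of 17 alternatives (adjusted p from 0.0052 to 0.40, log2 fold change from 0.50 to 0.69), and not with EIF1AY as a covariate, with limma-voom or with any 1 library left out. HDAC2 had 74.2 ± 3.43 CPM in VPA and 79.1 ± 1.37 in controls (adjusted p = 0.46), and HDAC3 44.1 ± 1.90 and 41.0 ± 1.92 (adjusted p = 0.51). The list of 29 deacetylase and acetyltransferase genes had a median of 0.04 and was not called (camera adjusted p = 0.21). HDAC1 alone passed over all genes and 2 were higher adjusted over the list alone.

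Of 21 genes of GABA and glutamate metabolism none passed over all genes, while 6 were higher and 3 lower adjusted over the list alone (median 0.10, camera adjusted p = 0.17). The glutamate transporter genes SLC1A3 and SLC1A2, also astrocyte markers, were among the 6. ALDH5A1, an enzyme gene of GABA breakdown named after its values were seen, was among the 3 (log2 fold change -0.23 ± 0.073, adjusted p = 0.16). GAD1 had 358 ± 9.32 CPM in VPA and 334 ± 9.29 in controls (adjusted p = 0.33). GAD2 had 60.3 ± 5.71 and 55.5 ± 2.72 (adjusted p = 0.50), and ABAT, the GABA transaminase gene, 171 ± 5.03 and 159 ± 10.1 (adjusted p = 0.40). The interneuron gene PVALB had a log2 fold change of -0.09 ± 0.084 (adjusted p = 0.67), the microglial gene AIF1 -0.18 ± 0.14 (adjusted p = 0.56) and the neurotrophin gene BDNF -0.22 ± 0.13 (adjusted p = 0.44). The axon guidance receptor gene PLXNB1 rose from 69.7 ± 6.64 to 97.6 ± 3.21 CPM (adjusted p = 0.041), in a list of 56 with a median of -0.02. CHRM3 was the called member of the 41 monoamine and acetylcholine genes (median 0.10), and TTR of the 15 choroid plexus and ependymal markers (median 0.12).

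The 31 lists that were not called included other cell types. Medians were 0.09 for 24 microglia markers, 0.03 for 18 endothelial markers and 0.13 for 20 mural cell and fibroblast markers. They were -0.02 for 13 upper-layer and -0.01 for 19 deep-layer neuron markers. Blood lists had 0.36 for 7 red blood cell markers and 0.57 for 11 peripheral leukocyte markers. Among neuronal lists they were -0.05 for 23 glutamate receptor genes and 0.02 for 33 neuropeptide and social hormone genes. They were 0.00031 for 30 immediate early genes and -0.0046 for 29 neurotrophin and growth factor genes. The 79 autism-associated genes had a median of -0.01, with 35 positive and 44 negative, none past the test over all genes and 1 higher adjusted over the list alone.

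Medians were 0.10 for 45 Wnt pathway genes, 0.09 for 32 extracellular matrix and perineuronal net genes, 0.07 for 19 DNA methylation genes. They stood at 0.04 for 23 cholesterol synthesis genes, -0.03 for 48 nuclear oxidative phosphorylation genes, -0.05 for 25 heat shock and chaperone genes. Others were at -0.03 for 29 antioxidant and detoxification genes and -0.02 for 20 circadian clock genes. They were 0.0034 for 32 cell division genes, 0.0084 for 32 apoptosis genes, 0.0026 for 27 complement genes. They reached 0.07 for 29 inflammatory cytokine and NF-kB genes and -0.06 for 25 glucocorticoid-responsive genes. The median, mean and test differed in sign in 10 lists, none of them called. These were heat shock, immediate early, antioxidant, neuropeptide, apoptosis, autism-associated, axon guidance, upper-layer, endothelial and neurotrophin genes.

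Adjusted over the list alone, 4 monoamine and acetylcholine genes were higher and 4 lower, against 2 and 3 neuropeptide genes, 1 and 3 heat shock genes and 3 and 1 axon guidance genes. Each other list that was not called had at most 3 such genes, apart from GABA and glutamate metabolism.

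In all, 13 of 44 lists were called with the preset correlation, 7 higher and 6 lower, and 0 with an estimated correlation. The other splits of the same 6 libraries called 8 to 18 lists with the preset correlation. The direction test fry passed glutamatergic neuron markers (adjusted p = 0.033, lower) and Wnt pathway genes (adjusted p = 0.016, higher). The Y-linked gene EIF1AY had 26.9 to 30.1 CPM in VPA 391, VPA 393, control 402 and control 408, and 0 and 0.111 CPM in VPA 392 and control 401. Among the 4 libraries with EIF1AY counts, edgeR called 0 genes (1919 at an unadjusted p under 0.05) and DESeq2 138 (26 among the 52). The direction of all 52 calls was kept there, as it had to be with groups that do not overlap. The medians there were 0.40 for oligodendrocyte, 0.21 for precursor and 0.12 for astrocyte markers. They were -0.12 for presynaptic genes, -0.18 for glutamatergic markers, -0.13 for GABA receptor genes and 1.31 for striatal markers. The other 2 libraries, 1 per group, were too few for a test.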

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

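The 3 settings with an EIF1AY selection or an oligodendrocyte score, and DESeq2 without VPA 393, were chosen after seeing the data. All 52 called genes kept their direction in every alternative listed here. As their groups do not overlap, leaving libraries out could not reverse that direction, and other thresholds reuse the same fold changes. The number called did not hold. From 52 genes (40 higher, 12 lower), it went to 141 (92 and 49) with no low-count filter and 168 (113 and 55) with robust dispersion. It was 30 (21 higher) with limma-voom, 444 (255 and 189) with DESeq2. It was 344 (215 and 129) at an FDR of 0.1, 2322 (1249 and 1073) at an unadjusted p under 0.05 and 3 (3 and 0) with a 2-fold minimum. Limma on FPKM called 2 (1 and 1) with a pseudocount of 1 or 0.1, PAMR1 and GFPT2, and 1 (1 and 0, PAMR1) without the FPKM filter, with 2055, 2057 and 2354 at an unadjusted p under 0.05. The EIF1AY covariate gave 62, with 19 lower and 41 among the 52; HDAC1, OSMR, PIP4K2C and OLFM3 lost their calls while their log2 fold changes moved by at most 0.0024. Leaving out 1 library gave 0 to 66 genes, 0 to 44 higher and 0 to 22 lower; fewer libraries were then tested, and only the removal of control 401 did not lower the count, though 27 of those 66 genes were among the 52. Without control 402 HBB, LOC100738859, GFPT2, PAMR1 and UBAP1L were called, and without control 408 PAMR1 and SEC16B, named here after their values were seen. The 4 libraries with EIF1AY counts gave 0 genes with edgeR (0 higher, 0 lower; 1919 at an unadjusted p under 0.05) and 138 (72 and 66) with DESeq2, 26 of them among the 52; without VPA 393 DESeq2 gave 410 (214 and 196), 47 of them among the 52. The oligodendrocyte score gave 0 (0 and 0; edgeR, 1083 at an unadjusted p under 0.05), in a fit with 1 more parameter. Over the named genes and their alternatives, 718 values kept their direction and side of the threshold, 200 lost the call, 29 gained it and 5 changed sign, all in genes that were not called: GFAP without VPA 392 (-0.067, with a range of -0.067 to 0.16 over the libraries left out) and in the EIF1AY libraries (-0.10), and PVALB (0.080), MBP (-0.14) and AIF1 (0.00039) with the oligodendrocyte score. The number of called lists was 13 (7 higher, 6 lower) in the main test and 0 (0 and 0) with an estimated correlation. Fry called 2 (1 and 1), and 1 of these, Wnt pathway genes, was not among the 13. With the oligodendrocyte score 8 lists were called (5 and 3), not all of them among the 13. Leaving out 1 library gave 10 to 16 lists, 4 to 11 higher and 5 to 7 lower. List medians changed sign for ribosomal proteins in the EIF1AY libraries (-0.0045), and for interferon-stimulated (0.037) and neurogenesis genes (-0.019) with the score. RLE, upper-quartile and library-size scaling and the 1 CPM filter kept the counts of genes within 1.5 times, and the share of higher calls within 10 percentage points under the scalings. Apart from these constructions, the cause was not tested. The planned fit without X and Y genes was not run, as the build behind the counts is not given in the sources used here. At 1 CPM a library holds 16 to 18 reads, so for DRD2 and SLC35D3 in controls counting error is large.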

Other observations

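The test of the glial lists with the oligodendrocyte score and the test of a like response in all VPA animals were chosen only after their results were seen, and the same score for the 49 glutamatergic and presynaptic genes, the gene length test and the second striatal list were added after the patterns they address had been seen.

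Blood-related transcripts differed between animals of the same group. HBB, a globin gene, had 124 to 198 CPM in the 3 VPA libraries and 204 CPM in control 402, but 23.1 CPM in control 401 and 46.7 CPM in control 408. ALAS2, a heme synthesis gene of red cell precursors, had 5.92 CPM in control 402, 0.389 in control 401 and 0.974 in control 408. In principal components of log2 CPM, the first component (30.045% of variance) placed VPA 392 (-23.0) and control 401 (-13.5), the libraries with almost no EIF1AY, at one end and control 402 (20.3) and control 408 (21.3) at the other, with VPA 391 (-2.28) and VPA 393 (-2.77) between. The second (23.6%) set VPA 391 (-14.7) and VPA 393 (-22.0) apart from control 401 (21.4), with VPA 392 at 2.84, control 402 at 5.05 and control 408 at 7.39, so that the 3 VPA libraries lay below the 3 controls.

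The number of called genes was 52 for VPA against control and at most 2 in the other splits of the 6 libraries into 3 and 3, where 1 of 10 splits, the real one, reached it. For gene lists called with the preset correlation it was 13 against a highest other value of 18, and 4 of the 10 splits, the real one included, reached 13. With 10 splits a share under 0.05 cannot be had for either count. The other splits called 8 to 18 lists.

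Glial lists stood higher and glutamatergic, synaptic and GABA receptor lists lower in VPA, though interneuron (median 0.15), upper-layer (-0.02) and deep-layer (-0.01) markers were not called, and a larger share of white matter in the VPA tissue is a candidate explanation. With the oligodendrocyte score as a covariate, the median log2 fold change of 49 glutamatergic and presynaptic genes was -0.13, as without it. It was -0.15 to -0.09 with each library left out. The score itself is higher in all 3 VPA libraries (6.99 to 7.19) than in any control (6.59 to 6.96), though VPA 393 and control 401 lay close. Because of this the fit cannot well separate white matter share from VPA. White matter share therefore stays open for these 49 genes. It also stays open for the glial part: the astrocyte median was 0.17 with the score (0.078 to 0.29 with each library left out), but the precursor median fell from 0.19 to 0.02 (-0.0042 to 0.064). Gene length bias is argued against, since removing the trend of fold change on length left medians of 0.31 (95% interval over genes 0.25 to 0.38) for oligodendrocyte markers and -0.16 (-0.19 to -0.12) for these 49 genes. The 13 called lists kept their direction and call with EIF1AY as a covariate. Libraries without EIF1AY were 1 per group, so this covariate could hardly move the fold changes, and the result says little about sex. Among the 4 libraries with EIF1AY counts the ribosomal median was -0.0045. A response to VPA, a difference in dissection and a litter difference remain open, as the design does not separate them.

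Striatal markers were high in VPA 393, and striatal tissue in that dissection is a candidate explanation. In a second list of 20 striatal genes written before their values were seen, 19 were measured, none shared with the first list, and 13 were highest in VPA 393; the median excess of VPA 393 over the other 5 libraries was 0.33 on the log2 scale. That was higher than in all 10000 random lists matched on expression, as striatal tissue would give. Random genes need not vary together as a marker list can, so the comparison does not tell striatal tissue from another shared change of these genes. The second list's most abundant genes moved less (ARPP21 0.14, CNR1 -0.08) than GNAL (1.98) and RXRG (1.12). Cortex also expresses most of both lists: 19 of 19 and 12 of 14 had at least 1 CPM in controls. A like response in all 3 VPA animals cannot be told apart from a smaller one. Without VPA 393 the first list's median was 0.47, against 1.16 with all libraries. Its 95% interval of 0.15 to 0.88 was taken over genes, not over animals.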
